A study of Homo sapiens with 24 samples.

How the data were processed

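Total RNA of the human intestinal epithelial cell line T84, a colon carcinoma line that grows as a polarised epithelium, was measured on 2-colour arrays of 8192 spots after infection with 1 of 8 strains of Vibrio cholerae. Per the labels, channel 1 of each array held RNA described as the epithelial cell line and channel 2 held RNA of cells infected with V. cholerae. There were 24 arrays, 3 for each strain. The time of infection, the dose of bacteria, the dyes, any dye swap, the scanner, the background correction and the normalization within arrays are not given in the sources used here. Whether the 3 arrays of a strain came from separate cultures is not given either, so p-values measure only the spread between these arrays, which may be technical.

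The deposited values are log2 ratios, as found from the values themselves, since the labels name no unit. All values equalled the log2 of a ratio in whole steps of 0.001 plus a constant of -0.57 that was the same for all 24 arrays (100% of values within 0.1 steps). The medians of the deposited log2 ratios ran from -0.84 to 0.24 over the arrays, and 11 of the 24 were above 0, so the arrays had not been centred on a common median. Their standard deviations ran from 0.39 to 0.95. No intensity came with the ratios, so signal over background is unknown and dim or saturated spots could not be left out. Of 196608 values, 165 were missing, 59 of them on 395 replicate 3, 49 on JBK70 replicate 1 and 45 on CVD110 replicate 3.

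The direction of the ratio is not stated. A positive value is likely infected over uninfected cells, since the labels name the infected cells as channel 2 and a test sample is usually set over its reference, but the dyes that would settle this are not given. All signs are those of the deposited values. "Above the reference", "higher" and "rose" refer to a positive sign, and "below", "lower" and "fell" to a negative sign. No pair of arrays had a correlation under -0.3 over all spots, and the lowest was -0.21.

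Gene names came from the platform annotation paired with the spots. It gave 1 gene symbol for 5560 spots, several for 94 and none for 2538, which are unnamed here. The gene identifiers of 14 spots with 1 symbol were not among those of the gene table, and their symbols were kept. Each array was centred on its median. Spots with the same single symbol were averaged, which gave 4725 named genes, 741 of them from more than 1 spot, and each other spot was kept as a feature of its own. Features with a value on at least 2 of the 3 arrays of each strain were tested, 7356 in all. Control spots are not identified in the annotation and were kept in the main analysis.

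A linear model with 1 mean per strain was fitted with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes) and 16 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all 7356 features within a comparison, with a threshold of 0.05, and intervals are 95% intervals of that model. The comparisons were the mean of the 8 strains against the reference, each strain against the reference, any difference among strains (an F test), and 9 contrasts between strains. The reference RNA was taken as the control, and no control sample was hybridised against it, so tests against the reference leave out the control's own spread. A dye effect that is the same on all arrays is part of these values and cancels between strains.

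The 21 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera on the 7234 features with a value on all arrays, with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. An estimated correlation and the rotation test fry, which tests a list against no change and not against the other genes, were alternatives. Named genes were the 10 largest log2 values above and 10 below the reference among genes past the threshold with all arrays on the same side, up to 4 genes past the threshold per list by smallest p, and a panel of 16 genes, of which 9 were measured under a single symbol. Where no gene passed, the 3 smallest p-values in each direction are given and said to be short of the threshold.

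The fit was tested on simulated data with the real variances. For 395 minus CVD101, over 7356 features, the simulation recovered 34% of features changed by a log2 of 1, 80% at 1.5, 88% at 2 and 98% at 3, with 11 false calls among 161. For the mean of the 8 strains against the reference it recovered 32% at 0.25, 94% at 0.5 and 100% at 1. The simulation drew independent errors for each array and held no batch.

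Alternatives planned before the data were examined were values as deposited, quantile normalization, stricter and no filters on missing values, each spot on its own, the replicate number as a block, robust variances, array weights, arrays or replicate numbers left out, and fits on only the arrays compared. A trend of the variance on signal level was not fitted, since ratios carry no level, and a floor or pseudocount was not needed for log2 values. Alternatives added after seeing the data were leaving out the 3 arrays that correlated least with the rest, leaving out 128 unnamed spots described with the results, centring within each of the 32 print blocks, scaling arrays to equal spread, testing against a log2 value of 1, and exchanging the numbers of 2 N16961 arrays whose labels conflict. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.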

Results

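Gene expression was profiled in T84 cells infected with 8 strains of V. cholerae, the bacterium that causes cholera. The strains were 395, a classical O1 Ogawa wild type; CVD101, derived from 395 by deletion of ctxA, the gene of the enzymatic A subunit of cholera toxin; and CVD103-HgR, a classical Inaba strain without ctxA and with a mercury resistance gene in hylA. El Tor strains were the Inaba wild type N16961, its derivative JBK70 without ctxA and ctxB, the Ogawa strain CVD110, and the nontoxigenic environmental isolate 1074-78. CVD110 lacks ctxA and the toxin genes zot and ace and has hylA interrupted. CVD112 is an O139 strain with the same deletions as CVD110. Each strain had 3 arrays, and their number limits the precision. Signal over background is unknown.

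Averaged over the 8 strains, the 3 genes farthest above the reference, among genes past the threshold with all arrays on the same side, were chemokine genes. CCL20, a chemokine that draws dendritic cells and lymphocytes, had a log2 ratio of 3.89 ± 0.99 (SD, n = 24 arrays), a 14.9-fold ratio. The neutrophil-attracting chemokine genes CXCL3 and CXCL1 followed, at 3.56 ± 1.06 and 3.41 ± 1.35. The nuclear receptor gene NR4A1, an immediate early gene, was at 2.71 ± 0.67 and the cytokine gene TNF at 2.29 ± 1.36. PHLDA1 (2.28), the MAP kinase phosphatase gene DUSP5 (1.90), TNFAIP3, an inhibitor of NF-kB signalling (1.89), the xenobiotic-metabolising CYP1A1 (1.89) and IER3 (1.87) completed the 10 largest. All 10 were above 0 on 24 of 24 arrays, which the rule that chose them required, with limma adjusted p-values from 5.8e-13 to 4.1e-07. The test took the 24 arrays as independent, but the arrays numbered 3 deviated from their strain means together (mean correlation 0.34). P-values and counts for the mean of the 8 strains can therefore be too optimistic.

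The genes farthest below the reference, chosen by the same rule, lay closer to 0. HLA-F, a nonclassical MHC class I gene, was at -1.69 ± 0.49, MLEC at -1.58 ± 0.55, the pseudogene NUS1P3 at -1.54 ± 0.68 and the keratin gene KRT14 at -1.49 ± 0.62 (SD, n = 24 arrays each). USP22, ASS1, BRD3, RETREG3, NEDD8 and EIF3B followed, from -1.41 to -1.23. All 10 were below 0 on 24 of 24 arrays, again as the rule required, with limma adjusted p-values up to 6.9e-05. Among the panel genes, IL6 was higher at 0.73 ± 0.84 and ICAM1, an adhesion molecule gene, at 0.47 ± 0.55, while the tight junction gene TJP1 was lower at -0.52 ± 0.68. IL1B was at 0.13 ± 0.33 and did not pass (limma adjusted p = 0.11). Without the replicate 3 arrays, IL6 was at 0.43 (adjusted p = 0.0045), while ICAM1 (log2 0.30, adjusted p = 0.077) and TJP1 (-0.32, adjusted p = 0.056) no longer passed. CXCL8, CXCL2, IL1A, NFKBIA, CFTR, ACTB and GAPDH were not among the spots with a single symbol and were not analysed here.

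In all, 4054 of 7356 features passed, 1863 above and 2191 below the reference. Against a log2 value of 1 in place of 0, a test added after seeing the data, 38 passed above and 9 below, of which 14 and 4 carry a gene symbol. As deposited, without centring, the split was 987 above and 2423 below, and with quantile normalization 1370 above and 3209 below. The median of all features lay at -0.13 as deposited and with quantile normalization. A ratio of 1 before the constant was added stands at -0.57 in the deposited values, and the source of that constant is not given. In these 2 scalings 0 is therefore not known to be equality with the reference. Their splits lie mostly below 0, but whether they lean to either side of the reference cannot be told. Without the replicate 2 arrays, with centring, 2630 passed. Values elsewhere are relative to centred arrays. All 128 unnamed spots in columns 9 to 16 of the last row of 16 print blocks passed above the reference, and 15 of them are among the 38 just given. Their mean was 1.26 ± 0.70 (SD over 24 arrays), and it was above 0 on 23 arrays.

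**Figure D1:**
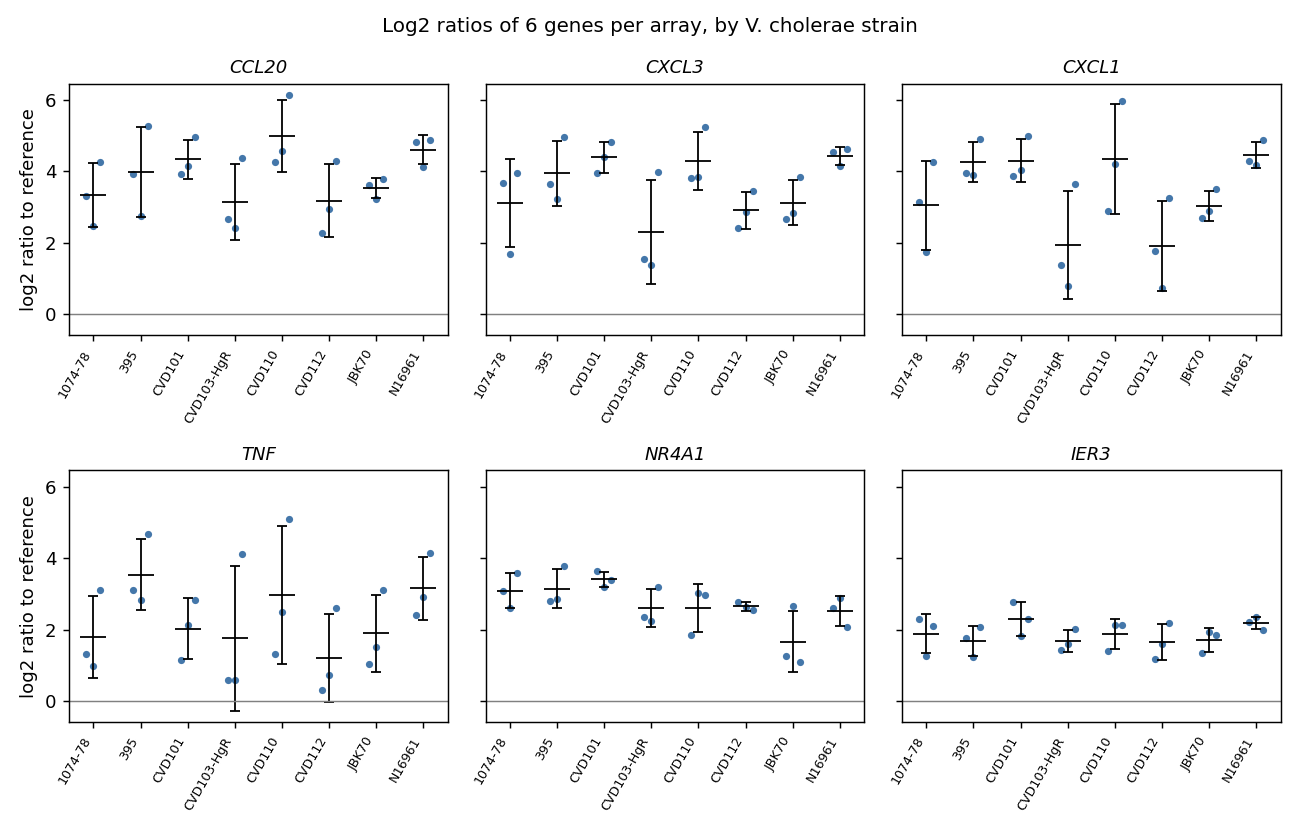
Log2 ratio to the reference (vertical axis) of 6 genes on each of 24 arrays, grouped by the strain that infected the cells (horizontal axis); points are arrays in the order of replicates 1 to 3, and bars show the mean and SD of 3 arrays. All arrays lie above 0 for the 6 genes, which the rule that chose them required, and the strain means of CCL20 run from 3.15 to 4.99.

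By gene list, 10 of 19 inflammatory cytokine and chemokine genes rose and 1 fell in the mean of the 8 strains, with the same counts adjusted over the list alone. Besides the chemokine genes named above, LTB, the gene of lymphotoxin beta, was higher (0.53 ± 0.29). The list stood above the other genes (camera adjusted p = 0.00094), with adjusted p = 0.14 with an estimated correlation. Of 20 immediate early and stress kinase genes, 12 rose and 3 fell, also adjusted over the list alone. Examples are NR4A1, DUSP5 and the AP-1 subunit gene FOSL1, at 1.44 ± 0.36, whose 2 spots read 0.56 and 2.31. That list had a median of 0.76 (camera adjusted p = 0.00041; adjusted p = 0.26 with an estimated correlation). Of 21 genes of cAMP signalling and CREB targets, 11 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.034; adjusted p = 0.26 with an estimated correlation). They included VEGFA, an angiogenic factor (0.71), PCK1, a gluconeogenic enzyme (0.85), and PRKAR1B, a regulatory subunit of protein kinase A (0.58). NR4A1 belongs to this list too. With arrays scaled to equal spread the cAMP list missed the threshold (adjusted p = 0.053). The list tests were not rerun with arrays or replicate numbers left out.

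On the arrays numbered 3, which stand apart from the others in several measures, the chemokine genes were higher still. CCL20, CXCL3, CXCL1 and TNF were each highest on the replicate 3 array of their strain in 8 of 8 strains. Their means over the 8 replicate 3 arrays were 4.75, 4.36, 4.43 and 3.71, against 3.47, 3.17, 2.91 and 1.59 over the other 16. The means over the other 16 also passed (limma, without replicate 3). TNFAIP3 was highest there in 5 of 8 strains, IER3 in 4 of 8 and NR4A1 in 3 of 8. IRF1 was highest there in 1 of 8, with a mean of 0.99 on replicate 3 against 1.75 on the others. The array titled as replicate 2 of N16961 has a description that names replicate 3, and the title was used. With the numbers of these 2 arrays exchanged, each of the 4 genes was highest on replicate 3 in 7 of 8 strains, and the counts of N16961 without replicate 2 and without replicate 3 given below change places.

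**Figure D2:**
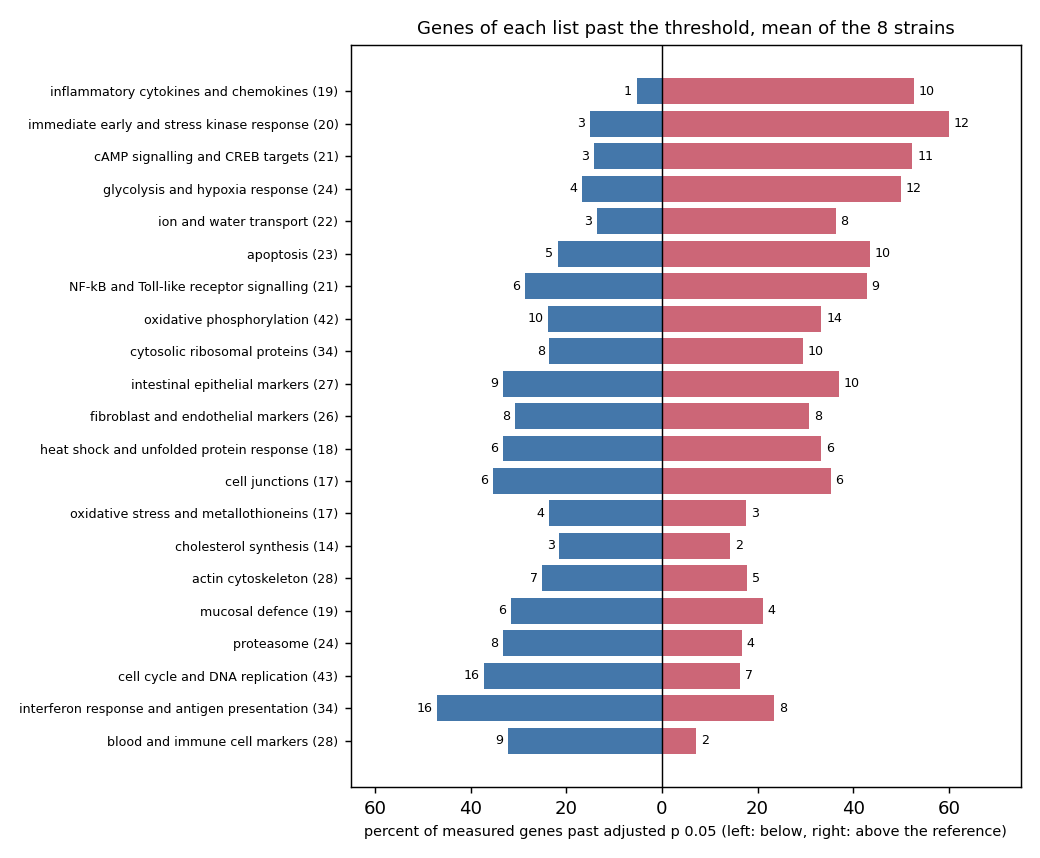
Share of the measured genes of each list past a limma adjusted p of 0.05 in the mean of the 8 strains, in percent (horizontal axis; left, below the reference; right, above it), with the number of genes at each bar and the number measured in brackets. The immediate early list has 12 of 20 genes above the reference, and the interferon and antigen presentation list has 16 of 34 below it.

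No other list passed in the mean of the 8 strains by camera, and their members went both ways. In NF-kB and Toll-like receptor signalling, 9 of 21 genes rose and 6 fell, with TNFAIP3 and NFKB2 (0.49) higher and the receptor-associated kinase gene IRAK1 (-0.83) lower (camera adjusted p = 0.39). In ion and water transport, 8 of 22 rose and 3 fell, with the kinase gene SGK1 (0.69) and the scaffold gene NHERF1 (0.39) higher and the anion exchanger gene SLC4A2 (-0.56) lower (adjusted p = 0.39). The 3 spots of SGK1 read from -0.08 to 1.13. Of 17 cell junction genes 6 rose and 6 fell. The claudin genes CLDN4 (1.59 ± 0.42) and CLDN3 (0.69) were higher, while CLDN7 (-0.62) and the E-cadherin gene CDH1 (-0.69) were lower (adjusted p = 0.96). In the actin cytoskeleton list, 5 of 28 rose and 7 fell, with LIMK2 (-0.59) and ACTN1 (-0.73) lower and the ezrin gene EZR (0.39) higher (adjusted p = 0.96). Of 23 apoptosis genes 10 rose and 5 fell, with the proapoptotic PMAIP1 (0.92) and BBC3 (0.87) higher and BIRC5, the survivin gene, lower at -1.05 (adjusted p = 0.43).

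Cell cycle and DNA replication had 7 of 43 genes higher and 16 lower, among them FEN1 (-0.74), AURKA (-0.80) and CCND2 (-0.98), with camera adjusted p = 0.43. Interferon response and antigen presentation had 8 of 34 higher and 16 lower, with IRF1 (2.83-fold) and IFI6 (0.75) higher and HLA-F and ISG20 (-0.58) lower (adjusted p = 0.39). Glycolysis and hypoxia response had 12 of 24 higher and 4 lower, with VEGFA, PGAM1 (0.51) and the glucose transporter gene SLC2A1 (0.42) higher (adjusted p = 0.12). The proteasome list had 4 of 24 higher and 8 lower, with PSMD14 at -0.84 (adjusted p = 0.37). Oxidative phosphorylation had 14 of 42 higher and 10 lower (adjusted p = 0.39), and cytosolic ribosomal proteins 10 of 34 higher and 8 lower, with RPS13 at 0.60 and RPS14 at -0.90 (adjusted p = 0.90). Heat shock and unfolded protein response had 6 of 18 on each side, with the transcription factor gene ATF4 lower at -0.88 (adjusted p = 0.98). Oxidative stress and metallothioneins had 3 of 17 higher and 4 lower, with PRDX1 at -0.68 (adjusted p = 0.76). Mucosal defence had 4 of 19 higher and 6 lower, with the mucin gene MUC1 at -1.13 and S100P at 0.46 (adjusted p = 0.98). Cholesterol synthesis had 2 of 14 higher and 3 lower, with MSMO1 at 0.72 and LSS at -0.63 (adjusted p = 0.96).

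Of 27 intestinal epithelial markers, 10 were higher, ELF3 among them (0.97 ± 0.35), and 9 lower (camera adjusted p = 0.98). Among markers of cells that the line should not hold, 2 of 28 blood and immune genes were higher and 9 lower (adjusted p = 0.76). Of 26 fibroblast and endothelial genes, 8 were higher and 8 lower, with VIM, which cultured epithelial lines can also express, at 0.99 ± 0.89 (adjusted p = 0.98). Adjusted over the list alone, the counts differed from those over all features for 4 lists. These were apoptosis (11 higher), interferon (17 lower), glycolysis (14 higher) and blood and immune markers (8 lower). For the cell junction, heat shock, mucosal defence and epithelial lists the median and mean lay below 0 while camera's direction was above. For the ribosomal and cholesterol lists the mean lay below 0 and the median and camera's direction above, and for the actin list the median lay above 0 and the mean and direction below.

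Each strain was compared with the reference to ask which responses appear with each infection. CCL20 passed in 8 of 8 strains, from 3.15 ± 1.07 in CVD103-HgR to 4.99 ± 1.01 in CVD110 (SD, n = 3; limma adjusted p at most 0.0019). CXCL3, NR4A1, PHLDA1, DUSP5, IER3, FOSL1 and CLDN4 also passed above the reference in 8 of 8 strains, and HLA-F, USP22 and EIF3B below it. CXCL1 and TNFAIP3 passed in 6 strains and TNF in 3, which were 395 (3.54), N16961 (3.15) and CVD110 (2.97), and the means of all 8 strains were above 0 for these 3 genes. These calls rested on few arrays. CCL20 and NR4A1 passed in each strain whichever array of that strain was left out, but TNF did not pass in N16961 when any 1 of its arrays was left out, nor in CVD110 without its replicate 2 (3.21) or replicate 3 (1.90). DUSP5 did not pass in N16961 when any 1 array was left out, though its value stayed between 1.90 and 1.98, so that call was lost with fewer arrays and not with a lower value. In CVD103-HgR it did not pass either, at values from 1.15 to 1.89. Of all refits of the named calls in single strains with 1 array of the strain left out, 518 of 1099 missed the threshold. No direction turned, which was fixed for the largest changes, since these were chosen with all arrays of the strain on the same side. IRF1 passed in CVD110 (2.84) and JBK70 (2.78), IL6 in 395 (1.80) and TJP1, below the reference, in JBK70 (-1.34), where its arrays read -2.38, -0.70 and -0.95. AVPR1A, a vasopressin receptor gene, was among the 10 largest in JBK70 (2.92), the Frizzled receptor gene FZD9 in CVD110 (2.64) and EDN2, an endothelin gene, in 395 (2.37). Below the reference, EIF4A1, a translation initiation helicase gene, was lowest in 395 (-2.88), RAD52, a recombination gene, in JBK70 (-2.95), and KRT19 in N16961 (-2.35) and CVD110 (-2.20). A gene that passed in some strains only is not shown to differ between strains.

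The inflammatory cytokine and chemokine list and the immediate early list stood above the other genes in 7 strains by camera. In JBK70 no list passed. For the cytokine list the estimated correlation left 395 (adjusted p = 0.033) and CVD101 (adjusted p = 0.044) past the threshold, with adjusted p from 0.050 to 0.17 in the other 5. For the immediate early list it left CVD101 (adjusted p = 0.044). The cAMP list stood above the other genes in 6 strains, without 395 and JBK70, and again only CVD101 was left (adjusted p = 0.044 with an estimated correlation). Other lists passed in CVD101 (NF-kB, glycolysis and oxidative phosphorylation, higher), CVD103-HgR (interferon, cell cycle and proteasome, lower), CVD112 (interferon, cell cycle, ribosomal proteins and proteasome, lower) and 1074-78 (proteasome, lower), and with an estimated correlation their adjusted p-values ran from 0.17 to 0.99. The number of features past the threshold was 1117 in 395 (471 above, 646 below), 1057 in JBK70 (355 above, 702 below), 259 in CVD110 (143 above, 116 below) and 236 in N16961 (116 above, 120 below). It was 232 in 1074-78 (114 above, 118 below), 161 in CVD103-HgR (68 above, 93 below), 120 in CVD112 (58 above, 62 below) and 90 in CVD101 (58 above, 32 below).

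The unnamed last-row spots made up 53 of the 114 above in 1074-78, 48 of the 143 in CVD110, 30 of the 116 in N16961, 25 of the 68 in CVD103-HgR, 26 of the 58 in CVD112, 96 of the 471 in 395, 92 of the 355 in JBK70 and 0 in CVD101. In CVD101 their mean was 0.96 and 0.86 on replicates 1 and 2, but -1.06 ± 1.65 (SD over spots) on replicate 3. Without these spots, 54 features were above and 98 below in 1074-78, 90 and 91 in CVD110, 70 and 91 in N16961, 42 and 83 in CVD103-HgR and 27 and 50 in CVD112. The same split was 385 and 592 in 395, 261 and 650 in JBK70 and 59 and 32 in CVD101.

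These counts depended on single arrays, on scaling and on whether the replicate number was a block (counts given below). Without replicate 1, 2 and 3 of the strain in turn, 816, 419 and 706 features passed in 395 and 381, 669 and 659 in JBK70. The same counts were 341, 83 and 81 in CVD110 and 50, 33 and 25 in N16961. They were 63, 93 and 64 in 1074-78 and 25, 68 and 48 in CVD103-HgR. In CVD112 they were 83, 181 and 55, and in CVD101 234, 29 and 21. With arrays scaled to equal spread, CVD101 had 605 and CVD112 had 0. The splits as deposited and with quantile normalization depend on the same unexplained constant. As deposited, the split above and below was 134 and 32 in N16961, 75 and 270 in 1074-78, 71 above of 210 in CVD110, 33 and 73 in CVD112 and 45 and 32 in CVD103-HgR. With quantile normalization 147 rose and 669 fell in 395, 121 and 457 in JBK70, 86 and 149 in CVD110, 276 and 720 in N16961, 188 and 662 in 1074-78, 185 and 671 in CVD103-HgR, 42 and 78 in CVD112 and 213 and 475 in CVD101. In JBK70, centring within print blocks gave 489 above and 623 below.

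No feature passed limma's F test for any difference among the 8 strains, with 146 of 7356 at an unadjusted p under 0.05, fewer than the 368 that chance gives for independent features. LDHC, TLK2 and KIF2C had the smallest p-values, all short of the threshold (adjusted p = 1.00). CXCL1, with strain means from 1.92 in CVD112 to 4.45 in N16961, had an unadjusted limma p of 0.0092. The model held no term for the replicate number, so deviations shared by arrays of 1 number add to its residual spread. This can make the F test and the contrasts between strains conservative. For the mean of the 8 strains against the reference, shared deviations can instead make p-values too small. With the replicate number as a block, no feature passed the F test, but the lowest adjusted p was 0.19. With array weights, whose estimation did not converge, 555 features passed the F test. Of 100 splits of the arrays into 8 groups, the real one included, 55 gave as many with weights, so chance is not excluded. Arrays of the same strain had a mean correlation of 0.41 over all spots and arrays of different strains one of 0.45. Only the latter include pairs that share a replicate number, so this does not show that strains leave no mark on the arrays.

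The comparison of toxigenic wild types with their ctx deletions asks what cholera toxin adds to the response of the cells. No feature passed in either pair, in their mean or in the difference between the pairs (limma, 0 of 7356 each). For 395 minus CVD101 the smallest p-values were those of the adenosine receptor gene ADORA1 (log2 1.36, 95% interval 0.66 to 2.06), the carbonic anhydrase gene CA4 (0.83) and C10orf12 (1.04) on the higher side and of FEN1 (-0.86), PFDN6 (-0.83) and ENOX2 (-1.12) on the lower side, all at adjusted p = 0.62. For N16961 minus JBK70 they were those of UCP2 (1.36), PPIP5K1 (1.35) and CCDC106 (1.05), and of AVPR1A (-2.96), TRAF3 (-1.35) and WNT5B (-2.80), at adjusted p = 1.00. Without JBK70 replicate 3, 7 features passed.

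In the mean of the 2 pairs, C10orf12 (0.65), CPM (0.70) and ADORA1 (0.71) led the higher side and IRF1 (-1.79, 95% interval -2.75 to -0.84), C8B (-0.85) and NLE1 (-0.41) the lower side, all at limma adjusted p = 1.00. For the difference between the pairs, LDHC (2.27), KIF2C (1.75), PFDN6 (1.12), CA4 (-1.10), SP4 (-1.05) and PROC (-1.31) had the smallest p-values (adjusted p = 0.94). CCL20 differed by 0.36 between wild types and deletions, with a 95% interval of -0.61 to 1.33, CXCL1 by 0.69 (-0.47 to 1.84) and TNF by 1.38 (-0.08 to 2.85), so differences of the size of these upper bounds are not excluded. At an unadjusted p under 0.05 there were 461 features for 395 minus CVD101, 161 for N16961 minus JBK70, 137 for their mean and 369 for their difference, beside 368 by chance. The median 95% interval of a contrast of a pair of strains reached 0.69 to either side. With array weights 145 features passed for 395 minus CVD101 and 15 for the difference between pairs. No other splits were fitted with weights for these contrasts, so chance is not excluded here either.

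By gene list, the immediate early list was higher in N16961 than in JBK70 (median 0.25, camera adjusted p = 0.0087), with 0 of 20 members past the threshold and adjusted p = 0.88 with an estimated correlation. No list passed for 395 minus CVD101, for the mean of the pairs or for their difference.

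The remaining contrasts compared biotypes, an environmental isolate and vaccine strains with further genetic changes, and no feature passed in any of them (limma, 0 of 7356 each). CVD103-HgR and CVD101 have different parents, as do CVD110 and JBK70, and CVD112 and CVD110 differ in serogroup. Differences in these contrasts can therefore not be assigned to the listed genes. For N16961 minus 395, which sets El Tor against classical wild type, ENOX2 (1.11), ITIH2 (1.15) and BTN2A2 (0.93) led the higher side. The cell cycle inhibitor gene CDKN2A (-0.95), PAX9 (-0.96) and ART4 (-1.79) led the lower side (adjusted p = 1.00; 191 features at an unadjusted p under 0.05). For 1074-78 minus N16961, BPIFA1 (1.09), ANXA13 (0.60), NEURL1 (0.93), S100A7 (-1.17), GOT1 (-0.51) and FHL2 (-0.39) led (adjusted p = 1.00; 34 features). For CVD103-HgR minus CVD101, SUPT16H (1.57), FMN1 (1.03), HHEX (1.17), CXCL3 (-2.09, 95% interval -3.45 to -0.73), DCTN2 (-0.97) and LTB (-0.60) led (adjusted p = 0.98; 236 features). For CVD110 minus JBK70, SNAPC3 (0.75), the lipid droplet gene PLIN2 (1.75), CXCR4 (1.21), AVPR1A (-3.17), WNT5B (-3.01) and TPM2 (-0.72) led (adjusted p = 1.00; 218 features). For CVD112 minus CVD110, SLC22A4 (1.21), MYF6 (1.43), CXCR6 (1.30), PYROXD1 (-0.82), PRIM1 (-0.79) and PDGFA (-0.82) led (adjusted p = 1.00; 203 features). With array weights 80, 2, 53, 170 and 2 features passed in these 5 contrasts, in the order given, again without splits to set these counts against.

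Several lists passed in these contrasts by camera with the preset correlation, with no single member past the threshold, and none with an estimated correlation. CVD103-HgR lay below CVD101 for 9 lists, with the lowest adjusted p for oxidative phosphorylation (median -0.28, adjusted p = 0.00012), proteasome (-0.32, adjusted p = 0.00025) and cytosolic ribosomal proteins (-0.31, adjusted p = 0.0018), and adjusted p = 0.57 for each of these 3 with an estimated correlation. The other 6 were interferon, intestinal epithelial markers, NF-kB, immediate early, cytokines and cell cycle. CVD112 lay below CVD110 for ribosomal proteins (-0.29, adjusted p = 0.0015), cytokines and oxidative phosphorylation and above it for blood and immune markers (0.29, adjusted p = 0.0045), with adjusted p from 0.90 to 0.92 with an estimated correlation. The immediate early list was higher in CVD110 than in JBK70 (0.19, adjusted p = 0.0054; adjusted p = 0.74 with an estimated correlation). The proteasome, cell cycle and NF-kB lists were lower in 1074-78 than in N16961 (adjusted p = 0.037 each; adjusted p from 0.56 to 0.85 with an estimated correlation). CVD112 replicate 1, CVD101 replicate 3 and CVD103-HgR replicate 1 had the lowest median correlations with the other arrays, at 0.12, 0.30 and 0.36, and belong to strains of these contrasts.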

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

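The scalings as deposited and by quantiles, the replicate block, array weights, fry, the estimated correlation and the single arrays and replicate numbers left out were chosen before the data were examined. Print-block centring, equal array spread, the removal of 3 arrays or of the 128 unnamed spots, and the test against a log2 value of 1 were chosen after seeing the data. Signal over background is unknown, so spots near background could not be told from bright ones, and the cause of the changes below was not tested. The replicate numbers do not pair the arrays by the rule used here, since the correlation of deviations from strain means ran from -0.09 to 0.58 for replicate 1, from -0.34 to 0.29 for replicate 2 and from 0.06 to 0.60 for replicate 3. By mean correlation, 19 of 24 arrays were closest to arrays of their own number, a hint from the data only. With the replicate block, 449 features passed in 1074-78, 1672 in 395, 391 in CVD101 and 398 in CVD103-HgR. The counts were 554 in CVD110, 308 in CVD112, 1578 in JBK70 and 610 in N16961. In the mean of the strains 4419 passed with the block, and no list's call by camera changed there. By fry with the block, ion transport (0.040), actin (0.040), apoptosis (0.048), oxidative stress (0.039), interferon (0.011) and cell cycle (0.032) were added.

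As deposited, 543 features passed in 395, 574 in JBK70, 52 in CVD101 and 77 in CVD103-HgR. With quantile normalization the counts were 850 in 1074-78, 688 in CVD101, 856 in CVD103-HgR, 578 in JBK70 and 996 in N16961. With equal array spread they were 541 in 1074-78, 427 in 395, 605 in CVD101, 884 in CVD103-HgR, 53 in CVD110, 0 in CVD112 and 749 in N16961. Without the 3 arrays of lowest correlation they were 350 in 1074-78, 30 in CVD101, 53 in CVD103-HgR, 487 in CVD110, 68 in CVD112 and 481 in N16961. Without the 128 unnamed spots they were 152 in 1074-78 and 77 in CVD112. Against a log2 value of 1, 47 passed in the mean of the strains, 1 in 1074-78, 5 in 395, 6 in CVD101, 4 in CVD110, 6 in N16961 and 0 in CVD103-HgR, CVD112 and JBK70. With array weights, whose estimation stopped before it converged, 2780 passed in 1074-78, 2138 in 395, 2903 in CVD101, 1710 in CVD103-HgR, 4348 in CVD110, 2741 in N16961 and 0 in CVD112. The weights ran from 0.012 for CVD112 replicate 3 to 11.2 for CVD110 replicate 2.

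With 1 array or 1 replicate number left out, the count ranged from 2630 to 4227 in the mean of the strains, from 21 to 93 in 1074-78, from 89 to 996 in 395, from 19 to 234 in CVD101, from 6 to 68 in CVD103-HgR, from 14 to 501 in CVD110, from 9 to 181 in CVD112, from 188 to 669 in JBK70 and from 17 to 118 in N16961. Where a replicate number was left out, each strain kept 2 arrays.

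Between strains the count stayed at 0 in all alternatives except array weights and the omission of arrays. With array weights it was 145 for 395 minus CVD101, 15 for the difference between the ctx pairs, 80 for N16961 minus 395, 2 for 1074-78 minus N16961, 53 for CVD103-HgR minus CVD101, 170 for CVD110 minus JBK70, 2 for CVD112 minus CVD110 and 555 for any difference. With arrays left out it ranged from 0 to 1 for 395 minus CVD101, from 0 to 7 for N16961 minus JBK70, from 0 to 2 for the mean of the ctx pairs, from 0 to 1 for N16961 minus 395, from 0 to 6 for CVD110 minus JBK70 and from 0 to 1 for CVD112 minus CVD110. The omitted arrays that gave calls were replicate 3 of 395, CVD110 or JBK70, and in CVD110 minus JBK70 also replicate 3 of all strains.

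Of the 3 lists past the threshold in the mean of the strains, 0 passed with an estimated correlation, at adjusted p = 0.14 for cytokines and 0.26 for the immediate early and cAMP lists. With print-block centring added these were 0.055, 0.17 and 0.055. The cAMP list also missed with equal array spread (0.053). The rotation test fry asks whether a list differs from no change, not from the other genes, so its p-values answer another question than camera. By fry 6 lists passed, with NF-kB (4.5e-05), glycolysis (0.0058) and proteasome (0.037) added. By fry with print-block centring, proteasome missed (0.064). Ion transport (0.014), cell junctions (0.014), apoptosis (0.046), oxidative stress (0.042), cell cycle (0.046) and cholesterol (0.025) passed there. The means of cell junctions and cholesterol were 0.046 and 0.019 there, but -0.11 and -0.13 with quantile normalization. Equal array spread added ion transport, actin, apoptosis, oxidative stress, interferon and cell cycle by fry (0.021 to 0.045). The next values depend on the constant of unknown source in the deposited ratios, since fry tests against 0 and neither scaling centres the arrays on it. By fry as deposited and with quantile normalization, NF-kB (0.13 and 0.13) and glycolysis (0.27 and 0.16) missed, while interferon (0.0013 and 0.00047), cell cycle (0.0012 and 0.00047) and oxidative stress (0.0074 and 0.00057) passed. With quantile normalization fry also passed cell junctions (0.0020), actin (9.6e-06), heat shock (0.0047), mucosal defence (0.00020), cholesterol (0.0062), epithelial (0.0041), blood (0.0014) and fibroblast markers (0.00066). Heat shock (0.39), mucosal defence (0.77), ribosomal proteins (0.97) and epithelial markers (0.86) lay below no change by fry, as their means did, and above the other genes by camera, which is no turn. By camera some lists turned direction without passing either way. As deposited, heat shock, mucosal defence and fibroblast markers turned (1.00 each), and with quantile normalization fibroblast markers (1.00). With print-block centring, alone or with an estimated correlation, heat shock, epithelial and fibroblast markers turned (1.00 each), and with equal array spread mucosal defence and epithelial markers (0.97 each).

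Of the 93 genes named for the mean of the strains, no sign turned in the alternatives refitted for them. Spots taken singly and the test against a log2 value of 1 were not among these, and SGK1, CSF1R, CAV1 and VWF each had spots on both sides of 0. Of the named calls in single strains, 659 of 1089 missed the threshold with 1 replicate number of all strains left out. CSF1R as deposited, and PMVK, CD48, ICAM1 and TJP1 without replicate 3, fell short of the threshold. No floor was tried, since log2 values need none, and no variance trend, since ratios carry no level.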

Other observations

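The families, the comparison with unnamed spots, the tests on replicate numbers and all counts of other splits were chosen after the results were seen.

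Gene families not fixed beforehand were looked at in the mean of the 8 strains. Among 16 keratin genes, 9 were below the reference and 1 above, with a median of -0.36 (camera adjusted p = 0.097; adjusted p = 0.38 with an estimated correlation). Among 25 cytochrome P450 genes, 10 were above and 0 below (adjusted p = 0.20), CYP1A1 with the largest value. Of 7 dual specificity phosphatase genes, a family that includes MAP kinase phosphatases, 4 were above and 2 below (camera adjusted p = 0.22). Of 5 claudin genes 4 were above and 1 below (camera adjusted p = 0.20). Of 12 MHC class I and II genes 2 were above and 6 below (adjusted p = 0.33), and of 14 histone genes 5 were above and 2 below (adjusted p = 0.20). Translation initiation factors (11 above, 10 below, of 28), S100 proteins (3 and 3, of 8), solute carriers (20 and 21, of 85) and zinc fingers (10 and 22, of 51) went both ways. None of the 10 families passed the threshold. The unnamed spots with the largest values outside the last rows were 250303 (2.63) and 140408 (2.45) above the reference and 250312 (-1.91) and 261412 (-1.82) below it.

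The 10 named genes farthest above the reference were set against the 128 unnamed spots in the last rows, whose mean was 1.26. If these spots hold no printed gene, they would show what a spot with little signal reads, and a ratio that rises as signal falls is a candidate explanation for values above the reference. All 10 genes exceeded the mean of these spots over the 24 arrays (sign-flip permutation test, two-sided, adjusted p up to 0.0093). The excess was 2.63 ± 1.26 for CCL20 and 2.30 ± 1.34 for CXCL3, and 0.61 ± 0.91 for IER3, which was above them on 18 of 24 arrays. Since the genes were chosen for their large values, this does not exclude little signal as a source of values above the reference. The 54 blood, immune, fibroblast and endothelial markers, which the line should express little, had a median of -0.11 (95% interval of a bootstrap over genes, -0.20 to 0.01). Of these markers, 10 were above and 17 below the reference, beside 1863 above and 2191 below among all 7356 features. Passing the threshold alone therefore does not show a response of the cells. The median of the markers goes against a rise at all dim spots. Without intensities it is not known that the spots of these markers were dim, so the explanation stays open. A dye effect on single genes stays open too, and what the 128 spots hold is not given in the sources used here.

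Arrays resembled each other whichever strain was used. The mean correlation within strains minus that between strains was -0.0399, and a one-sided permutation of strain labels over arrays gave p = 0.96. Pairs of 1 strain never share a replicate number, while some pairs of different strains do, and the permutation did not keep this structure. Deviations from strain means correlated at a mean of 0.34 between replicate 3 arrays, against -0.09 for pairs differing in number and strain. A shared number can thus raise the correlation between strains, so this test does not show that strains leave no mark. A response that all strains share and a dye or reference effect that all arrays share would both give the mean correlation of 0.45 between strains, and they cannot be told apart without dye-swapped arrays or uninfected cells set against the reference.

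The arrays numbered 3 deviated from their strain means together. The mean correlation of their deviations was 0.34 (one-sided permutation of numbers within strains, p = 5e-04), which is consistent with a batch that follows the replicate number. With the numbers of the 2 N16961 arrays of conflicting labels exchanged it was 0.17 (the same permutation test, p = 0.012). After centring within print blocks it was 0.343 (the same permutation test, p = 5e-04), which argues against offsets between print blocks as the whole cause. Position within a block, by row or column, is not removed by this centring and stays open. CCL20, CXCL3, CXCL1 and TNF were highest on this array in 8 of 8 strains (permutation within strains, adjusted p = 6e-04 each, 8 genes tested), by 1.28 ± 0.63, 1.19 ± 0.67, 1.52 ± 0.77 and 2.12 ± 0.82 (SD over 8 strains). The shift there was broad, though IRF1 was highest on this array in only 1 of 8 strains. The medians of 9 of the 21 lists were higher in 8 of 8 strains, by 0.45 ± 0.16 for ribosomal proteins, 0.42 ± 0.15 for proteasome, 0.36 ± 0.17 for interferon, 0.34 ± 0.15 for oxidative phosphorylation, 0.32 ± 0.15 for oxidative stress, 0.23 ± 0.09 for cytokines, 0.22 ± 0.11 for epithelial markers and 0.15 for actin and for glycolysis, while fibroblast and endothelial markers were higher in 1 of 8. No biological explanation was tested, since the labels give no condition that differs by number.

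For each contrast of a pair of strains, the 10 splits of the 6 arrays are too few for a share under 0.05. The real count was 0 in all 7, and the highest other split gave 0 in 5 of them, 1 for CVD110 minus JBK70 and 3 for CVD112 minus CVD110. For the mean of the ctx pairs, for their difference and for any difference among the 8 strains, 100 splits each were drawn. The real count was 0 in all 3, and the highest of the other splits was 0, 0 and 57. Since no split can fall below a count of 0, these comparisons say nothing about chance.

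Array weights gave the F test 555 features, but 55 of 100 splits of the arrays into 8 groups of 3, the real one included, gave as many. The median over the 99 other splits was 642 and the highest 4710, so chance is not excluded for the calls that array weights made among the strains. Splits that call several times the real count point to a structure of the arrays other than the strains or to the weights themselves, whose estimation had not converged, and which of these it was is untested.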
